A study of Mus musculus with 4 samples.

How the data were processed

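DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in mouse neural stem cells (NSCs) at passage 8. The 4 libraries form 4 groups of 1 library each: proliferating control, proliferating naloxone, differentiated control and differentiated naloxone. Naloxone is an opioid receptor antagonist. The titles of both differentiated libraries carry "D2", whose meaning the labels do not give. Per the labels' protocols, genomic DNA was digested with MspI, which cuts at CCGG, the fragments were end-repaired, ligated to methylated adaptors, selected by size, bisulfite-converted, amplified by PCR and sequenced from both ends.

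The authors deposited 1 cytosine report per library, with the counts of methylated and unmethylated calls at each listed cytosine of the mm10 genome. Per the submitters' processing notes, the tools were CASAVA 1.4, FastQC, Trim Galore 0.3.7, Bismark 0.9.0, Bowtie2, Bowtie and SAMtools, with no order or settings stated. The notes do not state whether duplicate reads were removed or how overlapping mates were handled. The deposited p-value columns were not used for any comparison. They follow a binomial model whose error rate, read back from the values, was 0.507% for proliferating control, 0.477% for proliferating naloxone, 0.559% for differentiated control and 0.473% for differentiated naloxone.

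The strand and sequence context printed beside each count belong to the base 1 position below the called cytosine. In proliferating control, calls at positions printed as CCG on the plus strand were 35.0% methylated, close to the 35.0% at positions printed there as CG. Positions printed as CG on the minus strand were 2.78% methylated, and those printed as CCG on the minus strand 2.65%. The counts were therefore paired with the context 1 base higher before CpGs were assembled, and the labels used as printed served as an alternative. Without the genome sequence, an offset of 1 base in the printed positions themselves could not be excluded, so each coordinate is exact to 1 base at best.

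Calls of both strands were summed per CpG. CpGs on the 19 autosomes and X with a depth of at least 10 in all 4 libraries were kept, which gave 955878 CpGs. Of these, 378043 lie in CCGG, 514997 lie outside it, and for 62838 the site class is not known. End repair fills in the MspI overhang with unmodified cytosine, so at CCGG 1 strand of a fragment end does not report the methylation of the cells. Comparisons were made over all CpGs, as planned, and repeated over the CpGs known to lie outside CCGG, which also leaves out those of unknown class, an alternative chosen after seeing the data.

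The gene table, from RefSeq on the assembly that mm10 names, holds no strand, so a gene-end window took the place of a promoter. It spans 1000 bp outward and 500 bp inward at the end of the gene with more measured CpGs, or at the lower coordinate when both had as many. The window is therefore at the 3' end for some genes. Of 34328 genes, 13897 had a window with at least 5 CpGs, and 4006 of those windows belong to genes with at least 5 CpGs at both ends. The level of a window is its methylated calls over all its calls, and 1995 windows are shared by 2 or more genes. Tiles of 1000 bp with at least 5 CpGs numbered 46078.

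Each comparison used a 2-sided Fisher's exact test on methylated and unmethylated calls, with Benjamini-Hochberg adjustment over all CpGs, windows or tiles. With 1 library per group the test compares those libraries, not the conditions, and no replicate check of any difference exists. A CpG was called at an adjusted p (q) under 0.05 and a difference of at least 25 percentage points, a window or tile at the same q and at least 10 points. A window or tile entered its test as 1 site of its mean CpG depth, because neighbouring CpGs share reads. The difference of the naloxone differences between proliferating and differentiated cells was tested per window with a z test on proportions. Its standard error was taken with 0.5 added to each count. Mean differences give every CpG the same weight, with 95% intervals from 1000 bootstrap draws of blocks of 1 Mb. Read-weighted means instead divide the methylated calls of each library by all its calls, so the weights of CpGs differ between libraries. Levels of single windows carry 95% Wilson intervals at the mean CpG depth. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error or sampling of CpGs only.

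The comparisons, tests, thresholds, 15 gene lists with 400 genes and the rule for named genes were fixed before the data were examined. The lists are neural stem and progenitor, neuronal, astrocyte, oligodendrocyte, DNA methylation machinery, opioid system, imprinted, germline genes, pluripotency, Hox, Notch, Wnt, Hedgehog and BMP signalling, mesenchymal and fibroblast, microglia and myeloid, endothelial, and cell cycle genes. For each list with at least 3 measured windows, the median difference was placed among 10000 random lists of the same size matched on mean methylation, as a description of these libraries. The rule names up to 10 called windows with the largest gain and 10 with the largest loss, called list members, up to 3 called tiles per direction, and 23 genes whether called or not. Of the 23 genes, 14 were measured. Oprm1, Oprk1, Dnmt1, Dnmt3a, S100b, Pou5f1, Nanog, Snrpn and Kcnq1ot1 had no window with enough CpGs. Other genes are named only where the text says that they were chosen after their values were seen.

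The alternatives chosen in advance were depth minimums of 5 and 20, CpGs measured in the compared libraries only, CpGs above the 99.9th percentile of depth left out, thinning to the lowest depth, each strand as its own site, autosomes only, windows of 500 and 2000 bp outward, at least 3 CpGs per window, counts summed over the CpGs of a window, equal weight per CpG, read-weighted means, correction for unconverted cytosines, tiles of 500 bp and unmatched random lists. Omission of CCGG, labels used as printed, summed counts outside CCGG, genes with under 5 CpGs at the other end, and lists and random lists with windows of the same CpGs counted once were added after seeing the data. Positions on Y were used only in the closing observations.

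The tests were tried on simulated data drawn from the real depths and levels. For naloxone against control in proliferating cells, 2% of 50 windows changed by 10 points were called, 80% of those changed by 20 points and 100% of those changed by 40 points. For the same comparison, 28% of 50 CpGs changed by 25 points, 64% changed by 40 points and 96% changed by 80 points were called, with 0 calls among 955678 unchanged CpGs. The simulated counts held binomial counting error only, so few calls among unchanged CpGs were fixed by construction. For differentiated against proliferating cells with naloxone, 10% of windows changed by 10 points and 64% of those changed by 20 points were called, with 2 calls among the unchanged CpGs. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and matplotlib 3.10.9 were used.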

Results

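CpG methylation was compared among 4 libraries of mouse NSCs, grown or differentiated with or without naloxone. The series concerns how naloxone relates to DNA methylation in these cells. The libraries held 499424045 cytosine calls for proliferating control, 410461326 for proliferating naloxone, 456785648 for differentiated control and 449711677 for differentiated naloxone. Over the 955878 CpGs measured in all of them, the median depth was 120, 81, 102 and 93 in the same order. Mean CpG methylation was 30.8%, 31.1%, 31.9% and 30.7%. Outside CCGG, Pearson's r across CpGs lay between 0.991 and 0.993 for every pair of libraries. CpGs are not independent replicates.

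Among the gene groups fixed in advance, neural stem and progenitor, imprinted and germline genes stood apart from each other in methylation. Gene-end windows of neural stem and progenitor genes were sparsely methylated, with a median of 3.44% over 25 windows in proliferating control (0.576% over 23 windows outside CCGG). There the intermediate filament gene Nes stood at 3.99% (95% interval 1.94 to 8.06%, mean depth 172), the pluripotency and neural factor Sox2 at 1.45% (0.153 to 12.3%, depth 34.6) and the oligodendrocyte lineage factor Olig2 at 5.53% (3.19 to 9.42%, depth 217). Outside CCGG these 3 stood at 0.555%, 0.723% and 3.33%. Germline genes were mostly methylated, with a median of 76.6% over 21 windows (91.7% over 17 outside CCGG). Among them, the germ cell RNA-binding gene Dazl stood at 76.3% (68.1 to 82.9%, depth 124), and outside CCGG at 91.7%, above that interval. Imprinted genes lay between these, with a median of 51.0% over 23 windows, of which 21 are distinct because Peg3 and Usp29, and Peg10 and Sgce, share their CpGs (54.2% over 15 distinct windows outside CCGG). At Peg3 the level was 43.8% (36.5 to 51.4%, depth 168), and at the imprinted non-coding gene H19 it was 51.8% (45.4 to 58.0%, depth 238), and neither had enough CpGs outside CCGG for a level there.

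Lineage markers, signalling genes and opioid genes mostly had low methylation at the ends measured. In proliferating control the median was 6.02% for neuronal, 5.27% for astrocyte, 6.26% for oligodendrocyte, 3.47% for DNA methylation machinery, 4.33% for opioid system and 7.72% for pluripotency genes. It was 6.55% for Hox, 4.02% for Notch, Wnt, Hedgehog and BMP signalling, 6.11% for mesenchymal and fibroblast, 11.4% for endothelial and 3.61% for cell cycle genes. The microglia and myeloid list had 1 measured window, at Irf8, with 4.17%. Outside CCGG the medians of these lists with at least 3 windows lay between 0.593% for cell cycle and 4.47% for Hox genes, except for endothelial genes, with 24.4% over 4 windows. The delta opioid receptor gene Oprd1 (mm10 chromosome 4, 132143987 to 132145486) stood at 7.98% (4.69 to 13.3%, depth 158) and the enkephalin gene Penk (chromosome 4, 4138316 to 4139815) at 5.68% (1.40 to 20.3%, depth 29.3). The dioxygenase genes Tet1, Tet2 and Tet3 stood at 3.64%, 3.75% and 2.61%, the methyltransferase gene Dnmt3b at 2.68% and the neuronal tubulin gene Tubb3 at 8.76%. Outside CCGG these were lower: 2.44% at Oprd1, 3.70% at Penk, 0.220%, 0.250% and 0.222% at Tet1, Tet2 and Tet3, 0.455% at Dnmt3b and 3.10% at Tubb3. The astrocyte filament gene Gfap stood at 57.1% (51.2 to 62.9%, depth 274) and at 72.7% outside CCGG, at the lower-coordinate end of the gene, which the gene table cannot show to be its promoter.

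**Figure D1:**
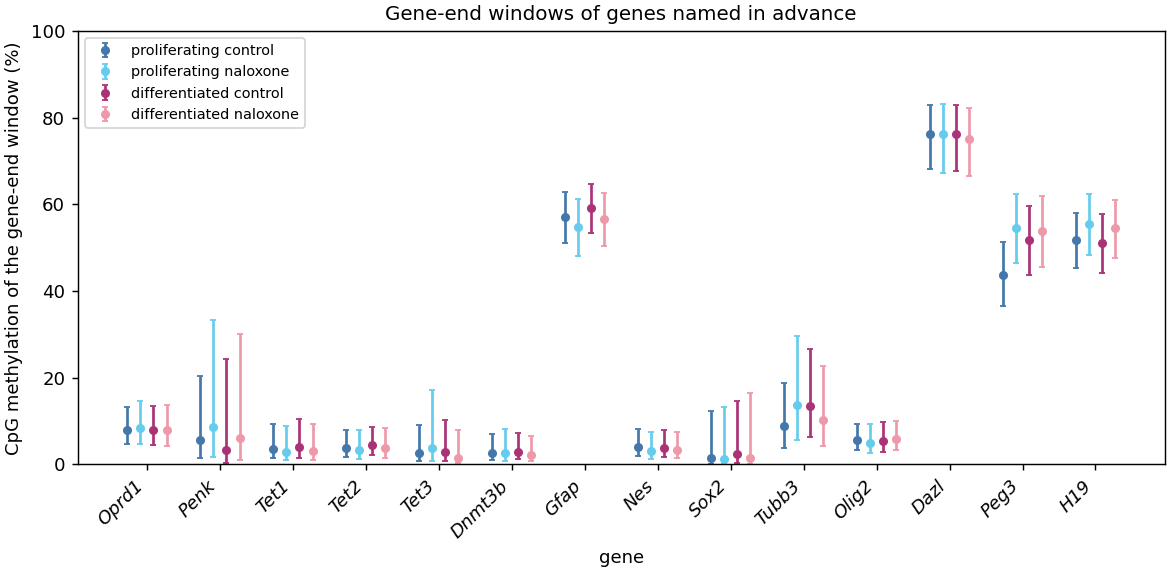
CpG methylation (%) of the gene-end window of each gene named in advance, over all its CpGs with CCGG included, with 1 point per library and 95% Wilson intervals at the mean CpG depth. Nes, Sox2 and the Tet genes sit near 0, Dazl near 76.3%, and Peg3 and H19 between 43.8% and 55.5%, with overlapping intervals for all libraries at each gene.

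On chromosome X, gene-end windows were methylated to an intermediate level that autosomal windows seldom had. Over 157 X windows with at least 10 CpGs outside CCGG the median was 29.8% in proliferating control, 30.3% in proliferating naloxone, 33.1% in differentiated control and 32.2% in differentiated naloxone. Over 9243 autosomal windows it was 0.743%, 0.732%, 0.840% and 0.727%. Under 10% methylation were 2.55% of the X windows and 90.7% of the autosomal ones in proliferating control. The fragile X gene Fmr1, chosen after its values were seen, stood at 27.2% over all its CpGs in that library (mm10 chromosome X, 68677536 to 68679035).

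**Figure D2:**
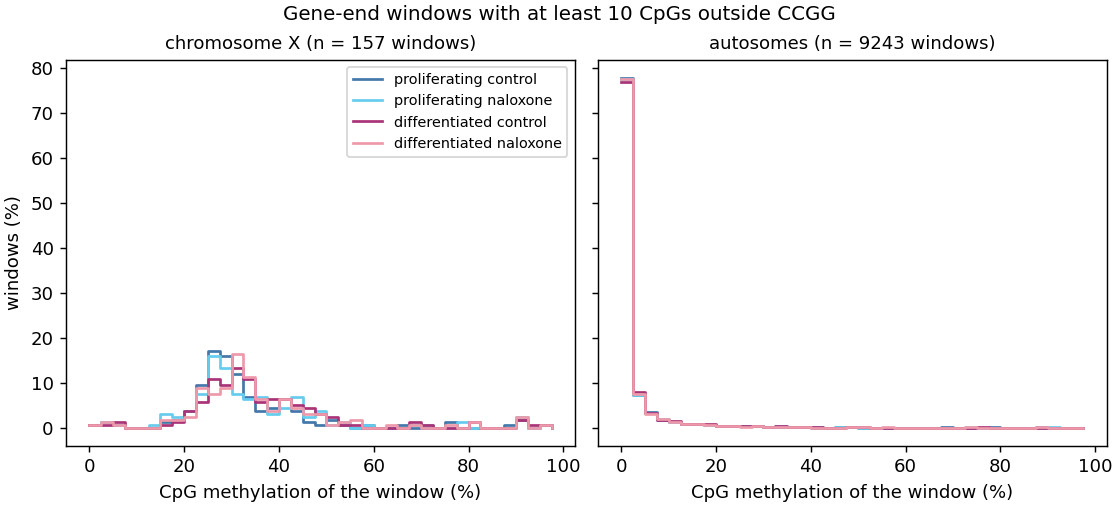
Distribution of gene-end windows (% of windows, y axis) by CpG methylation (%, x axis) on X and on autosomes, CpGs outside CCGG only, with 1 line per library. The X windows centre near 30.3% while most autosomal windows lie near 0.

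CpGs at the MspI sites themselves behaved unlike all others. In proliferating control the methylation of top and bottom strand had an r of -0.314 across 340051 CpGs at CCGG, and 61.6% of them differed by at least 25 points between strands. Across 363981 CpGs outside CCGG, r was 0.981 and 1.47% differed that much. Between the strands of that library the CpG test called 1876 of them, and 2406 of 322442 in differentiated naloxone. Those counts exceed the calls between libraries outside CCGG given below. Counts thus differ between the strands of 1 culture for reasons other than the culture. Whether such differences recur in every library was not tested. The strand counts therefore do not give how many calls to expect between libraries. In the other libraries r at CCGG lay between -0.287 and -0.278. CCGG holds 39.5% of the CpGs compared, so each comparison is given over all CpGs and, as an addition made after seeing the data, over the CpGs outside CCGG with q adjusted over those alone.

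**Figure D3:**
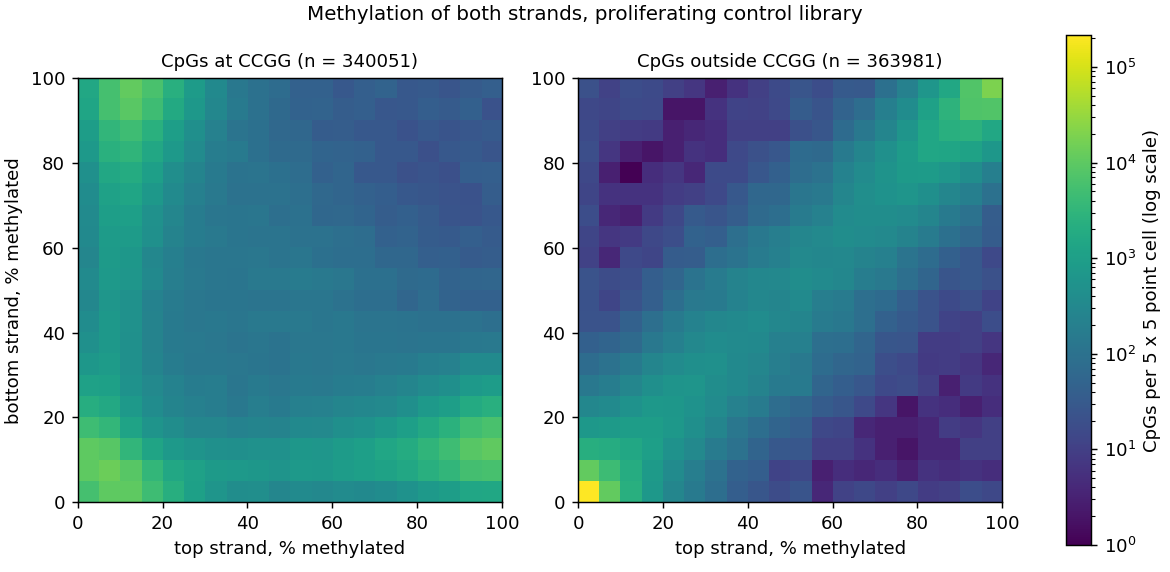
Methylation of the top strand (%, x axis) against the bottom strand (%, y axis) per CpG in proliferating control, at CCGG (n = 340051) and outside CCGG (n = 363981). Colour gives the number of CpGs per cell on a log scale. Outside CCGG the CpGs follow the diagonal, while at CCGG many have mostly methylated calls on 1 strand only, where end repair affects the calls.

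Between naloxone and control in proliferating cells, few sites and 0 gene-end windows were called. Outside CCGG, 11 CpGs rose and 6 fell. The CpGs named here were chosen after their values were seen. A CpG in Etv5, which encodes an ETS transcription factor, rose from 7.63% to 34.5% (chromosome 16, position 22430368, depths 236 and 165, q = 6.39e-08). A CpG in Bcor, which encodes a BCL6 corepressor, rose from 7.55% to 50.0% (depths 53 and 38, q = 0.0168), and a CpG in Fanca, a gene of the Fanconi anaemia pathway, fell from 85.6% to 53.3% (depths 153 and 75, q = 0.00168). CpGs in Ttc39a, Kbtbd11, Onecut3, Zbtb7c, Prr15l and Jade3 also rose, and CpGs in Ascc1, Rps6kl1, Mta3 and Frmpd4 also fell.

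Over all CpGs, 739 rose and 522 fell, and 1135 of these 1261 calls lay at CCGG. Of the 13897 gene-end windows, 0 were called as 1 site each, 8 had an unadjusted p under 0.05, 25 were at least 10 points higher and 17 as much lower, and 97.4% differed by less than 5 points. The opioid genes gave no call: Oprd1 differed by 0.402 points (q = 1) and Penk by 2.96 points (q = 1). Tet1, Tet2, Tet3 and Dnmt3b differed by -0.760, -0.559, 1.21 and -0.169 points, and Nes, Sox2, Tubb3 and Olig2 by -0.861, -0.145, 4.86 and -0.600 points, all with q = 1. Gfap differed by -2.41, Dazl by -0.126, Peg3 by 10.7 and H19 by 3.75 points, also with q = 1. Outside CCGG, Tet1 and Dnmt3b had the other sign (0.172 and 0.204 points), and Tubb3 differed by 0.598 points. The fatty acid ligase gene Acsl4 (chromosome X, 142390303 to 142391802), chosen after its values were seen, had 23.8% in control and 47.2% with naloxone at depths of 59.8 and 39.4 (unadjusted exact p = 0.0272, q = 1). The imprinted gene Mcts2, chosen likewise, had 51.0% and 34.7% (unadjusted exact p = 0.0503, q = 1).

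Of the 14 lists with at least 3 windows, the imprinted genes alone lay outside the central 95% of random lists in this comparison. Their median difference was 1.95 points, at percentile 98.7, with 15 of 23 windows higher and 0 called. With windows of the same CpGs counted once, a choice made after seeing the data, they lay inside (1.70 points, percentile 95.7, 13 of 21 higher), as they did outside CCGG (0.591 points, percentile 26.6). Counted for each list adjusted over the list alone, 0 windows were called, as over all windows. The single tile called over all CpGs lay in Zc3h7a, which encodes a zinc finger protein (chromosome 16, 11144001 to 11145000), and rose from 46.7% to 62.3% (q = 4.00e-123). Its mean depth was 13413 and 10625, against depths of 917 and 913 that only the deepest CpGs of these libraries exceeded, and reads of multi-copy sequence could not be excluded there. Outside CCGG a tile in Gm19951 (chromosome 12, 99645001 to 99646000) was called too, from 63.3% to 74.5% (depths 1120 and 804, q = 0.000733). The mean over CpGs was 0.356 points higher with naloxone (95% interval 0.340 to 0.370), and 0.488 points outside CCGG (0.467 to 0.508). Outside CCGG it was 1.13 points between genes, where control stood at 67.8%, and 0.143 points in gene-end windows, where control stood at 5.69%. Weighted by reads, the difference over all CpGs was 1.72 points (1.59 to 1.89). Summing counts over each window called 20 windows higher and 12 lower.

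Between naloxone and control in differentiated cells, few sites were called and mean methylation was lower with naloxone. Outside CCGG, 2 neighbouring CpGs rose and 1 fell, named here after their values were seen. The pair lies 237887 and 237892 bp from Kdm4c, a histone demethylase gene, and rose from 45.03% to 73.4% (q = 0.0344) and from 47.4% to 78.9% (q = 0.00167) at depths of 171 and 109. The third, 40445 bp from the predicted gene Gm29924, fell from 80.2% to 43.3% (depths 111 and 134, q = 5.93e-05). Over all CpGs, 3 rose and 7 fell, and 5 of these 10 calls lay at CCGG, all of them lower.

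Again 0 gene-end windows were called, with 4 at an unadjusted p under 0.05 and 97.9% within 5 points. Oprd1 differed by -0.00334 and Penk by 2.80 points, and outside CCGG both had the other sign (0.162 and -1.54 points), as did Nes (0.138 points). Tet1, Tet2, Tet3 and Dnmt3b differed by -0.871, -0.724, -1.38 and -0.790 points, and Nes, Sox2, Tubb3 and Olig2 by -0.349, -0.9997, -3.25 and 0.328 points. Gfap differed by -2.49, Dazl by -1.03, Peg3 by 2.13 and H19 by 3.44 points, and q was 1 for each of these 14 genes. Outside CCGG the difference was smaller at Tet1, Dnmt3b, Gfap and Tubb3 (-0.113, -0.200, -0.503 and -1.10 points). It was larger there at Tet2, Olig2 and Dazl (-0.863, 1.37 and -2.23 points). The imprinted non-coding gene Airn, chosen after its values were seen, had 69.9% in control and 46.9% with naloxone (unadjusted exact p = 0.144, q = 1). The chromatin remodelling gene Smarca1, chosen likewise, had 35.2% and 21.1% (unadjusted exact p = 0.0177, q = 1).

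Every list with at least 3 windows except the oligodendrocyte genes had a median below 0, and 3 lists lay above matched random lists. Median differences were -0.409 points for Hox genes (percentile 98.5, 21 of 30 lower), -0.216 points for imprinted genes (percentile 99.5, 12 of 23 lower; -0.400 points, percentile 97.7 and 12 of 21 with windows of the same CpGs counted once) and 0.00404 points for oligodendrocyte genes (percentile 99.4, 5 of 11 lower). Outside CCGG each of these lay inside the central 95%, as did the other lists. The median over all windows was -0.695 points. Lower were 24 of 25 neural stem and progenitor, 22 of 23 cell cycle, 22 of 23 neuronal and 11 of 12 astrocyte windows, lists that lay inside the central 95%. These counts include CCGG, where the mean over CpGs differed by -2.10 points. Outside CCGG the medians of these lists were -0.0910, -0.141, -0.402 and -0.261 points in the same order. Calls at cytosines outside CpGs followed by A, C and T were 1.40%, 1.02% and 0.567% methylated in differentiated control. With naloxone they were 1.20%, 0.827% and 0.478%. Whether unconverted cytosines account for these medians was not tested. No member of any list was called, also when adjusted over the list alone. The mean over CpGs differed by -1.20 points (95% interval -1.22 to -1.19), and by -0.580 points outside CCGG (-0.599 to -0.562). Outside CCGG it was -1.36 points between genes, where control stood at 69.3%, and -0.199 points in gene-end windows, where control stood at 6.02%. Weighting CpGs by their reads turned the mean difference over all CpGs to 0.00686 points (-0.0491 to 0.0607), and summing counts called 6 windows higher and 19 lower.

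Between differentiated and proliferating control cells, methylation was mostly higher in differentiated cells. Outside CCGG, 7 CpGs rose and 0 fell, and 5 of the 7 were on X, all named here after their values were seen. X held 11309 of the 514997 CpGs outside CCGG, but 23.3% of the gene-end windows with 20 to 80% methylation there. A CpG 8 bp from Zbtb33, which encodes the transcription factor Kaiso, rose from 19.7% to 60.5% (depths 76 and 43, q = 0.0374). A CpG in Cul4b, a ubiquitin ligase scaffold gene, rose from 45.2% to 78.7% (depths 104 and 89, q = 0.00629), and a CpG in Ddn, the dendrin gene, rose from 2.63% to 45.2% (depths 38 and 31, q = 0.0427). The others lay in Ccdc17, Lancl3, Gm32261 and Prps2. Over all CpGs, 101 rose and 16 fell, and 79.5% of these calls lay at CCGG.

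No gene-end window was called, and 12 had an unadjusted p under 0.05. Oprd1 differed by -0.173 and Penk by -2.46 points. Tet1, Tet2, Tet3 and Dnmt3b differed by 0.322, 0.656, 0.251 and 0.259 points, and Nes, Sox2, Tubb3 and Olig2 by -0.243, 0.932, 4.74 and -0.112 points. Gfap differed by 2.08, Dazl by -0.0403, Peg3 by 7.89 and H19 by -0.688 points, and q was 1 for each of these 14 genes. Outside CCGG, Oprd1, Gfap, Tubb3 and Dazl had the other sign (0.229, -0.163, -0.565 and 2.34 points). Fmr1, chosen after its values were seen, had 27.2% in proliferating and 43.4% in differentiated cells (unadjusted exact p = 0.0207, q = 1). Ppp1r3f on X, a phosphatase subunit gene chosen likewise, had 47.9% in proliferating control and 62.7% to 66.6% in the other libraries. The window of AY036118, chosen likewise, passed the q threshold (q = 3.75e-10) but not the minimum difference, with 26.9% and 31.4% at depths of 11620 and 12380, where multi-copy sequence could not be excluded.

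Imprinted genes had a median difference of 4.17 points (percentile 99.99 of matched random lists, 16 of 23 higher). With windows of the same CpGs counted once, it was 2.96 points (percentile 98.4, 14 of 21 higher). Oligodendrocyte genes (0.00674 points, percentile 1.62) and opioid system genes (-0.185 points, percentile 0.030) lay below the random lists. Outside CCGG none of these lay outside the central 95%, while the DNA methylation machinery did, at percentile 99.94 with a median of 0.483 points over 17 windows. Its X-linked member Zbtb33, chosen after its values were seen, had 30.6% in proliferating cells and 40.6% in differentiated cells. No member of any list was called, also when adjusted over the list alone. The mean over CpGs was 1.14 points higher (95% interval 1.12 to 1.16), and 0.725 points outside CCGG (0.703 to 0.748), where it was 2.77 points on X (2.41 to 3.14) and 0.680 points on autosomes. Among windows with 20 to 80% methylation the median difference was 3.50 points on X and 2.33 points on autosomes, and that contrast was not tested. Outside CCGG a tile 106370 bp from Gm36166 (chromosome 8, 20122001 to 20123000) rose from 39.0% to 49.9% (depths 1406 and 1180, q = 9.17e-05). Summing counts over windows called 40 higher and 1 lower.

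Between differentiated and proliferating cells with naloxone, single sites went both ways and mean methylation was slightly lower in differentiated cells. Outside CCGG, 6 CpGs rose and 4 fell, named here after their values were seen. At Rgs16, which encodes a regulator of G protein signalling, 4 CpGs rose between positions 153740351 and 153740378 of chromosome 1. Each had a depth of 122 in proliferating naloxone and of 199 or 200 in differentiated naloxone, so the same reads may cover all 4. The first rose from 29.5% to 59.5% (q = 0.00110). A CpG in Sim2, a transcription factor gene, rose from 17.9% to 71.4% (depths 39 and 35, q = 0.0215), and a CpG in Nacad fell from 51.5% to 22.2% (depths 130 and 153, q = 0.00172). The remaining calls lay near Gm16506, which was higher, and Gm35433, Gm29924 and Gm30821, which were lower. The site near Gm29924 was also lower against differentiated control, a comparison that shares the differentiated naloxone library.

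Over all CpGs, 614 rose and 800 fell, and 95.4% of these calls lay at CCGG. No gene-end window was called, and 3 had an unadjusted p under 0.05. Oprd1 differed by -0.578 and Penk by -2.62 points. Tet1, Tet2, Tet3 and Dnmt3b differed by 0.211, 0.491, -2.35 and -0.361 points, and Nes, Sox2, Tubb3 and Olig2 by 0.269, 0.0774, -3.37 and 0.816 points. Gfap differed by 2.00, Dazl by -0.940, Peg3 by -0.671 and H19 by -0.998 points, and q was 1 for each of these 14 genes. Outside CCGG, Oprd1, Tet2, Sox2 and Dazl had the other sign (0.361, -0.0089, -0.127 and 0.268 points), and Penk differed by -8.33 points. The zinc finger gene Zfp180, chosen after its values were seen, had 33.6% in proliferating and 46.5% in differentiated cells (unadjusted exact p = 0.0119, q = 1). Opioid system genes lay below matched random lists (median -0.699 points, percentile 0.380, 11 of 14 lower, 0 called, also when adjusted over the list alone), at percentile 24.0 outside CCGG. All other lists lay inside the central 95%. The mean over CpGs differed by -0.420 points (95% interval -0.436 to -0.405), and by -0.343 points outside CCGG (-0.362 to -0.324). Weighted by reads, the difference over all CpGs was -0.149 points (-0.285 to -0.0605). Summing counts over windows called 20 higher and 8 lower.

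The naloxone differences of proliferating and differentiated cells, which share no library, had correlations near 0. Their sign differed between the sets of regions and, across tiles over all CpGs, between the coefficients. Across 46078 tiles Pearson's r was 0.0204 (95% interval 0.00355 to 0.0353) and Spearman's rho -0.0129 (-0.0231 to -0.00308), with 48.1% of tiles of the same sign. Outside CCGG r was -0.0182 (-0.0469 to 0.0123) and rho -0.0732 (-0.0898 to -0.0560), with 47.2% of the same sign. Across gene-end windows outside CCGG r was 0.0424 (-0.0293 to 0.104) and rho 0.00686 (-0.0163 to 0.0299). Outside CCGG the mean naloxone differences varied with level. They were 1.35 points in proliferating and -1.56 points in differentiated cells at CpGs over 80% methylated, and -0.000490 and -0.119 points under 10%. The correlations were not taken within levels, so they do not separate such shifts from agreement of single regions. For the state differences with and without naloxone, which also share no library, r across tiles was 0.0443 (0.0276 to 0.0596) and rho -0.00829 (-0.0185 to 0.00159), with 45.8% of the same sign. Across gene-end windows outside CCGG r was 0.144 (0.0786 to 0.205) and rho 0.0330 (0.00898 to 0.0566), with 49.8% of the same sign. They shared 4 CpGs called higher and 1 called lower, where independent lists would share 0.0649 and 0.0134, and 0 called outside CCGG. The z test of the difference of naloxone differences called 0 gene-end windows taken as 1 site each, with 6 at an unadjusted p under 0.05 and 138 apart by at least 10 points, and 74 with counts summed. Neural stem and progenitor genes had a median difference of differences of -1.18 points (percentile 0.150), and oligodendrocyte genes 0.114 points (percentile 97.9). Outside CCGG they lay at percentiles 27.4 and 62.2.

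**Figure D4:**
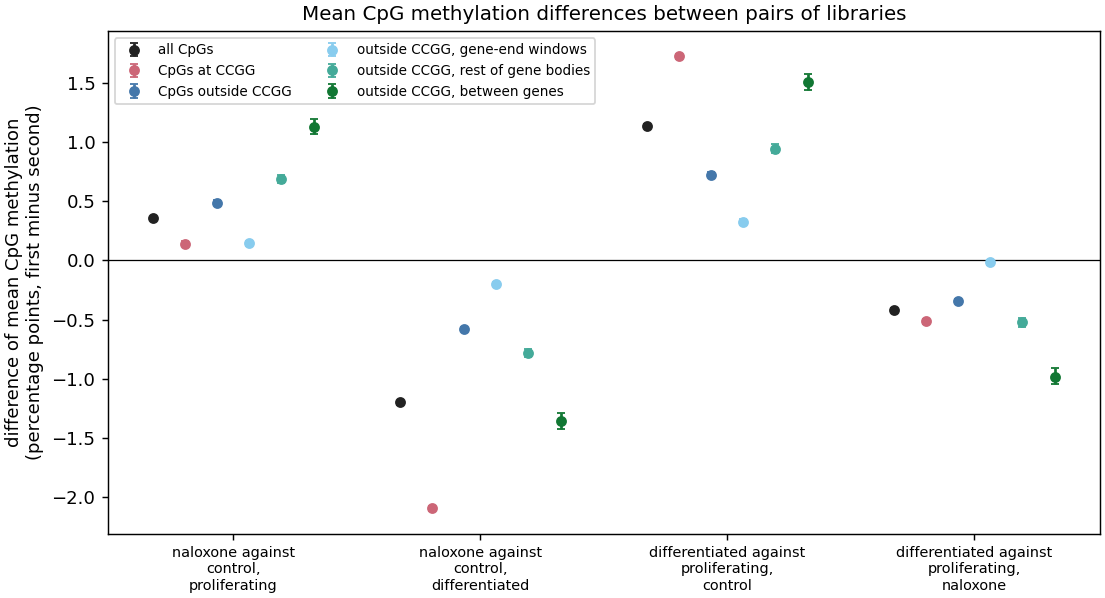
Difference of mean CpG methylation (percentage points, y axis) in each comparison (x axis), first group minus second, for all CpGs, CpGs at CCGG, CpGs outside it and regions outside it. Bars are 95% bootstrap intervals over blocks of 1 Mb. Outside CCGG the naloxone difference is above 0 in proliferating cells (0.488 points) and below 0 in differentiated cells (-0.580 points). It is larger between genes than in gene-end windows, whose methylation is also lower (67.8% and 5.69% in proliferating control).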

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

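For the differences at CCGG, the tests of depth and of neighbouring CpGs were chosen only after the result was seen, and so were the tests of unconverted cytosines and of the number of libraries for the mean naloxone difference, while the test of CpGs of like depth was added once that difference was known, with its prediction written before its own value was seen.

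The naloxone difference of mean methylation had opposite signs in the 2 states with each CpG weighted the same. With CpGs weighted by the reads of each library, CCGG included, it was 1.72 points in proliferating cells. In differentiated cells it was then 0.00686 points (-0.0491 to 0.0607). Those weights differ between libraries, so these 2 values also depend on where the reads of each library fell. With equal weights a block bootstrap of the difference of differences separated it from 0: it was -1.56 points over all CpGs and -1.07 points outside CCGG (95% interval -1.10 to -1.04), and it was below 0 in 1798 of 1879 blocks of 1 Mb with at least 50 CpGs outside CCGG. For the mean outside CCGG, unconverted cytosines were argued against as the whole cause. After correction with each library's share of methylated calls outside CpGs, 90.2% of that difference of differences was left. At CpGs there under 10% methylated it was -0.119 points before correction (-0.133 to -0.105), and in gene-end windows -0.341 points. The correction was not made for either alone, and the share outside CpGs was highest in differentiated control. Unconverted cytosines therefore stay open as a cause at those CpGs and windows. A difference in depth at the CpGs themselves was argued against too, since 97.8% (95% interval 95.8 to 99.8%) was left among 169860 CpGs whose highest depth was at most 1.5 times their lowest, relative to CpGs of the same mean methylation. Whether naloxone acted differently in the 2 states, or any 2 cultures or library preparations differ this much, cannot be told apart with 1 library per group.

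CpG calls between libraries lay mostly at CCGG, above all in the 2 comparisons with the proliferating naloxone library. There, 99.2% of the CCGG CpGs called (2464 of 2484) moved against the share of calls from the less methylated strand, which is consistent with a shift in strand shares instead of in methylation of the cells. Methylation of the whole fragment was argued against, since CpGs outside CCGG within 50 bp moved by a median of 0.367 points, against 29.8 points at the called CpGs. After each CpG was thinned to its lowest depth, 75.6% of the number of calls was left (2021 of 2675). Thinning the summed counts keeps the expected level of each CpG, so it could not test whether depth per strand made the differences. Over all CCGG CpGs with calls on both strands, the mean share of the less methylated strand was 49.9% to 50.1% in each library. The shares thus differ at single sites and not across whole libraries. Why they differ at those sites was not tested, and no biological explanation was tested apart from a change of the whole fragment.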

How the results depend on the processing

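The settings that leave CCGG out, use the labels as printed, combine CCGG omission with summed counts, leave out genes with enough CpGs at both ends, or count windows with the same CpGs once were chosen only after the result was seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of the CpG counts, 47 stayed within 1.5 times the reported value and 25 did not. Of the window counts 57 stayed and 17 did not, and of the mean differences 31 kept their direction and 1 did not. Of the list medians, 8 left the random range and 7 entered it with the same sign. With CCGG left out, 15 of 56 list medians had the opposite sign, 3 of them of lists that lay outside the random range. Unless stated, the cause was not tested. In the following, proliferating and differentiated stand for naloxone against control in those cells, and the state comparisons are differentiated against proliferating.

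In differentiated cells, a depth of at least 20 gave 5 CpGs higher, and leaving out the deepest CpGs gave 1 higher and 3 lower. Thinning gave 0 higher there, 58 higher and 7 lower for the state comparison in control, and 408 higher for that with naloxone; thinning leaves fewer reads by construction. With each strand as its own site, 110 CpGs were higher and 72 lower in proliferating cells, and 64 higher and 85 lower for the state comparison with naloxone. With CpGs at CCGG and those of unknown class left out, as in each setting without CCGG, the counts were 11 higher and 6 lower in proliferating cells, 1 lower in differentiated cells, 7 higher and 0 lower for the state comparison in control, and 6 higher and 4 lower for that with naloxone; fewer CpGs are tested by construction. With labels used as printed, the counts were 401 higher and 247 lower in proliferating cells, 13 lower in differentiated cells, 167 higher and 37 lower for the state comparison in control, and 374 higher and 393 lower for that with naloxone.

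With counts summed over the CpGs of a gene-end window, 20 windows were higher and 12 lower in proliferating cells, 6 higher and 19 lower in differentiated cells, 40 higher and 1 lower for the state comparison in control, and 20 higher and 8 lower for that with naloxone. The z test of the difference between states then called 74 windows. With CCGG left out as well, the counts were 38 higher and 7 lower, 8 higher and 13 lower, 39 higher and 6 lower, and 25 higher and 11 lower, in the same order. Summing gives more calls by construction, because it counts a read once per CpG.

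The mean naloxone difference in differentiated cells turned to 0.00686 points when CpGs were weighted by reads. The agreement of the naloxone comparisons had an r of 0.0150 with tiles of 500 bp, no longer apart from 0, and of -0.0182 with CCGG left out. With CCGG left out, the medians of the 3 lists outside the random range that turned went to -0.0798 points for oligodendrocyte and 0.0244 points for opioid system genes in the state comparison in control, and to 0.197 points for imprinted genes in differentiated cells with naloxone. Counting windows with the same CpGs once took the imprinted genes in proliferating cells into the random range, with a median of 1.70 points. Of windows simulated with a change of 10 points, the least that can be called, 2% to 14% were called as 1 site and 30% to 54% with counts summed.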

Other observations

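The non-CpG comparison and the levels at Y genes were chosen only after the result was seen, and the way of reading the test of Y CpGs was set only after its value was known.

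Cytosines outside CpGs, measured only on the top strand where another C precedes them, had a sequence order that was the same in all libraries. In proliferating control, 1.25% of calls were methylated at cytosines followed by A, 0.849% at those followed by C and 0.496% at those followed by T. In differentiated control the values were 1.40%, 1.02% and 0.567%, the highest of the libraries in each class. With naloxone they were 1.23%, 0.847% and 0.480% in proliferating cells, and 1.20%, 0.827% and 0.478% in differentiated cells. Unconverted cytosines add to these values, and no spike-in was held to measure them.

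The intermediate methylation of X windows raised the hypothesis that each culture held both XX and XY cells. All libraries had calls in the first 4 Mb of Y, 12350 in proliferating control, 11469 in proliferating naloxone, 12648 in differentiated control and 11528 in differentiated naloxone. It was predicted that over 50% of Y CpGs outside CCGG in CpG-dense tiles would be under 10% methylated, unlike X. That prediction was not met: the share was 5.36% in proliferating control, 0% in proliferating naloxone, 7.41% in differentiated control and 5.56% in differentiated naloxone, over 54 to 56 CpGs. On X it was 6.96% to 7.60%, while the medians were 88.3% to 89.5% on Y and 34.4% to 38.7% on X. How methylated Y CpGs are does not show how many cells carry Y, so this test could not tell whether both kinds of cells were present. The median depth of these CpGs was 29.5 to 43.5 on Y and 65 to 92 on X. The question is left open. The gene-end window of the Y-linked demethylase gene Kdm5d was 8.79% methylated in proliferating control (330 calls over 10 CpGs), and that of Usp9y 69.6% (56 calls over 5 CpGs). Their 95% Wilson intervals, 6.19 to 12.3% and 56.7 to 80.1%, counted every call as independent. They are therefore narrower than intervals at the mean CpG depth, which the other windows carry.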
